A study of Mus musculus with 12 samples.

How the data were processed

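The data are 12 mouse RNA libraries made by SC3-seq, a method that amplifies cDNA and sequences the 3′ ends of mRNA, here from 1 ng of total RNA each on a SOLiD instrument, per the labels' protocols. They come from 6 cell lines with 2 culture replicates each. GSC_1 and GSC_2 are germline stem cells (GSCs), which are spermatogonial stem cells expanded in culture, from testes of separate animals at postnatal day 7. GSCLC_1 to GSCLC_4 are germline stem cell-like cells (GSCLCs) taken from reconstituted testes in culture. GSCLC_1 and GSCLC_4 came from testes kept at 34°C for 3 weeks, called condition 1 here. GSCLC_2 and GSCLC_3 came from testes kept at 37°C for 2 weeks and then at 34°C for 1 week, called condition 2. All lines were grown in one serum-poor medium with GDNF, FGF2, LIF and EGF, and all carry an acrosin-promoter EGFP reporter on one mixed strain background, per the labels.

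The authors deposited 1 table of RPM (reads scaled to one common total per library) for 26219 genes in the 12 libraries. The tools cutadapt 1.3, TopHat 1.4.1 and Cufflinks 2.2.0 and the mouse build mm10 (GRCm38) were used, per the submitters' processing notes, whose roles and parameters are not given in the sources used here. Whether counting used the strand is not given in the sources used here, so reads of a gene and of an antisense partner may not have been told apart. The RPM of each library sum to 999885 to 999962, so the table does not show depth directly. The low RPM values lie on even steps, and between 99.7% and 99.9% of them were whole multiples within 0.1 of a step. The step sizes of 0.215 to 0.33 RPM imply 3031705 to 4644178 counted reads per library. This recovery was not complete for all genes, so count-based tests were not run and the implied depth is used only to describe precision. A floor of 3 reads corresponds to 0.646 to 0.99 RPM and covers counting error only, since amplified reads without molecular identifiers are not independent molecules. Across the 2 libraries of a line, a chi-square statistic on the implied reads came to 3.95 to 8.45 per gene, so culture replicates differed by more than counting noise and none was treated as a duplicate.

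Genes with at least 5 RPM in at least 2 libraries were tested, which left 11788. Values were taken as log2(RPM + 1), and every fold change below is on this scale, which understates the change of low genes. The line was taken as the independent unit, because the labels describe each line as derived separately, and the 2 libraries of a line were averaged. Independence of the lines was not tested. The kind of line coincides with its source, a postnatal or a reconstituted testis, so effects of the 2 cannot be told apart. GSCLC and GSC lines were compared with limma 3.58.1 in R 4.3.3, with variances moderated along a mean-variance trend, as 4 lines against 2. Conditions 2 and 1 were compared in the same way as 2 lines against 2, in a fit that also held the GSC lines so that all 3 groups shared one estimate of the spread. Each GSCLC line was also compared with the mean of both GSC lines, and GSC_2 with GSC_1, with limma on single libraries; these p-values rest on the spread between culture replicates of a line and do not speak for other lines. P-values are two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Distances between lines were compared by a one-sided exact permutation test over the 15 ways to pick 2 of the 6 lines.

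A set of 23 gene lists was fixed before the data were examined, as were the tests, the main alternatives and the rule for the genes to be named. The lists cover self-renewal of spermatogonial stem cells (SSCs), spermatogonial differentiation, meiotic prophase, spermatids, the germ cell core, the piRNA pathway, primordial germ cells, pluripotency, DNA methylation, imprinted genes, Sertoli cells, Leydig and peritubular cells, fibroblasts, macrophages and endothelium, heat shock, p53 targets, the G2/M phases of the cell cycle, the response to FGF and GDNF, glycolysis, cholesterol synthesis, Hox genes, the Y chromosome and the interferon response. The 21 lists with at least 5 tested members were tested against all other genes with camera in limma, with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. The spermatid list had 4 members past the filter and was not tested as a set. Genes of the Y chromosome were not analysed here.

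The genes named for each group comparison are, per direction, the 8 with the largest change among those past the threshold, with at least 20 RPM in the higher group and no overlap of line means. To these were added the members of each list past the threshold, at most 6 per list. Where fewer than 5 genes passed, the 8 per direction with the smallest unadjusted p were named as not passing. A set of germ cell and pluripotency genes was given in every case. For each single line, the 3 genes with the largest change per direction were named. Predicted gene models were counted but not named, and not every gene that the rule picks is given in the text.

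The gene identifiers in the table, which are Entrez numbers, were matched to the RefSeq annotation of GRCm38 for coordinates, which are counted from 1; 24619 of 26219 matched, and 11411 of the 11788 tested. The last 300 bases of the transcripts of 84 named genes were searched against all GENCODE M21 transcripts with blastn 2.17.0, run from Python 3.11.15, for matches of at least 95% identity over 200 bases. Matches were found for 7 genes, and the genome outside transcripts was not searched. Figures were drawn with matplotlib 3.10.9. The alternatives were other pseudocounts, filters, scalings and variance models, fits on single libraries, the replicate number as a block, and each library or line left out in turn.

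The tests were tested on simulated data with the spread of these lines and 100 genes changed by 2-fold and 100 by 4-fold. The comparison of GSCLC with GSC lines recovered 49% and 87% of them on 11462 genes. That of the conditions recovered 24% and 86% on 11453 genes. The spread in the simulation was set gene by gene after a first version with one spread for all genes. It was too wide for the 2 GSC lines, as given below, so the recovered shares are approximate.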

Results

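Transcript levels were measured in 12 libraries from 6 mouse cell lines, with 2 culture replicates per line. The lines are 2 GSC lines, 2 GSCLC lines of condition 1 and 2 GSCLC lines of condition 2. The RPM steps imply 3031705 to 4644178 counted reads per library. Between 15895 and 16529 of 26219 genes were above 0 in a library, and the 10 most abundant genes took 3.79% to 4.88% of the RPM. Levels below are means over lines in RPM ± SD, with n = 2 for GSC and n = 4 for GSCLC lines, and log2 changes are given ± SE from limma with its Benjamini-Hochberg adjusted p. The labels describe the replicates of a line as biological replicates of the culture.

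The first question was how close the GSCLC lines came to the GSC lines as a whole. Germ cell genes were high in all 6 lines, such as Dazl, an RNA-binding protein of germ cells, at 1293 ± 21.7 RPM in GSC and 1424 ± 75.4 RPM in GSCLC lines, and Ddx4, a germ cell RNA helicase, at 478 ± 78.6 and 521 ± 34.4 RPM. Over the tested genes, Pearson's r between 2 libraries averaged 0.972 within a line, 0.968 between the GSC lines and 0.94 between a GSC and a GSCLC library. These are correlations across genes, which are not independent replicates. Among the GSCLC lines r averaged 0.956 across conditions and 0.952 within a condition. The mean Euclidean distance between a GSC and a GSCLC line was 62.8, against 50.4 between lines of one kind. The difference of 12.4 gave p = 0.0667 in a one-sided exact permutation test, the smallest p that the 15 splits of 6 lines allow.

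Between GSCLC and GSC lines, 143 genes were higher and 213 lower in GSCLC lines, and 248 of these 356 changed by over 2-fold. Among called genes of at least 20 RPM in the higher group, large rises included that of Sfi1, a centrosome protein, from 22.6 ± 7.37 to 198 ± 42.1 RPM (log2 3.12 ± 0.21, adjusted p = 3.03e-05). Crym, which encodes a thyroid hormone-binding protein, rose by 2.97 ± 0.32, the imprinted amino acid transporter gene Slc38a4 by 2.64 ± 0.26 and Spsb4, a substrate adaptor of a ubiquitin ligase, by 2.55 ± 0.23. Blnk, an adaptor of B cell receptor signalling, rose by 2.50 ± 0.35, Prelid2 by 2.49 ± 0.37 and the lysosomal peptidase gene Tpp1 by 2.12 ± 0.20. The largest falls, again among genes of at least 20 RPM in the higher group, were those of Cyp11a1, the first enzyme of steroid synthesis, Chrna4, a subunit of the nicotinic acetylcholine receptor, and Lat, an adaptor of T cell receptor signalling. Chrna4 went from 56.4 ± 17.1 to 4.46 ± 2.38 RPM (log2 -3.49 ± 0.40, adjusted p = 0.00131) and Lat from 31.8 ± 2.3 to 3.48 ± 2.33 RPM (-3.13 ± 0.41, adjusted p = 0.00314). Mapk10, a JNK kinase, fell by 2.78 ± 0.67 on the log2 scale with adjusted p = 0.048. Tdrd9, a helicase of the piRNA pathway, fell by 2.76 ± 0.53 and Pou5f1, the pluripotency factor also known as Oct4, by 2.56 ± 0.49. On GRCm38, Sfi1 (identifier 78887) lies on chromosome 11 at 3131850 to 3203347, Crym (12971) on chromosome 7 at 120186380 to 120201989 and Chrna4 (11438) on chromosome 2 at 181022311 to 181043579.

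All 356 genes had line means of log2 values that did not overlap between GSC and GSCLC lines. In RPM those of T overlapped, at 32.6 in GSCLC_3 and 32.4 in GSC_2. Separation on the log2 scale was seen for 28.6% of the genes tested, where chance gives 13.3%. The count rests on the 2 GSC lines: without GSC_2 it was 12, with 11 rises and 1 fall against 143 and 213, and without GSC_1 it was 42, with 19 rises and 23 falls, with the remaining GSC line assumed to vary like the others. Sfi1, Crym, Slc38a4, Spsb4, Prelid2 and Tpp1 were among the 12, while Mapk10 passed in 13 of its 32 alternative settings.

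Of the SSC self-renewal list, 6 of 28 tested members fell, 0 rose and 22 did not pass, and adjusted over the list alone 11 fell and 1 rose. Lhx1, a homeobox gene induced by GDNF, went from 106 ± 0.203 to 30.6 ± 9.3 RPM (log2 -1.83 ± 0.26, adjusted p = 0.00458). Egr2 (-1.12 ± 0.15) and Bcl6b (-0.98 ± 0.14), which GDNF also induces in these cells, fell with adjusted p = 0.00417 and 0.00451. The T-box genes Eomes (-1.66 ± 0.34) and T (-2.44 ± 0.58) and the POU factor gene Pou3f1, from 81.0 ± 2.52 to 41.2 ± 10.0 RPM, fell with adjusted p = 0.0239, 0.0453 and 0.0339. T stood at 58.5 RPM in GSCLC_3 replicate 1 against 6.74 to 8.52 RPM in the other libraries of condition 2. T passed in 15, Pou3f1 in 20 and Lhx1 and Egr2 in 30 of 32 alternative settings. Without GSCLC_3 replicate 2, Bcl6b, Pou3f1, Eomes and T no longer passed, with adjusted p = 0.0624, 0.102, 0.209 and 0.242. The list as a whole was lower by camera with adjusted p = 1.8e-05, and adjusted p = 0.183 with an estimated correlation. Other regulators of SSC maintenance did not pass. Gfra1, the GDNF receptor, stood at 331 ± 27.2 RPM in GSC and 309 ± 40.9 RPM in GSCLC lines (log2 -0.11 ± 0.14, adjusted p = 0.73). The change was -0.12 ± 0.12 for the receptor kinase gene Ret, -0.16 ± 0.14 for Etv5, 0.25 ± 0.14 for Zbtb16, -0.38 ± 0.16 for Id4 and -0.50 ± 0.28 for Nanos2, with adjusted p from 0.265 to 0.659. The last 300 bases of Gfra1 also occur in a predicted transcript, so its level is uncertain.

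**Figure D1:**
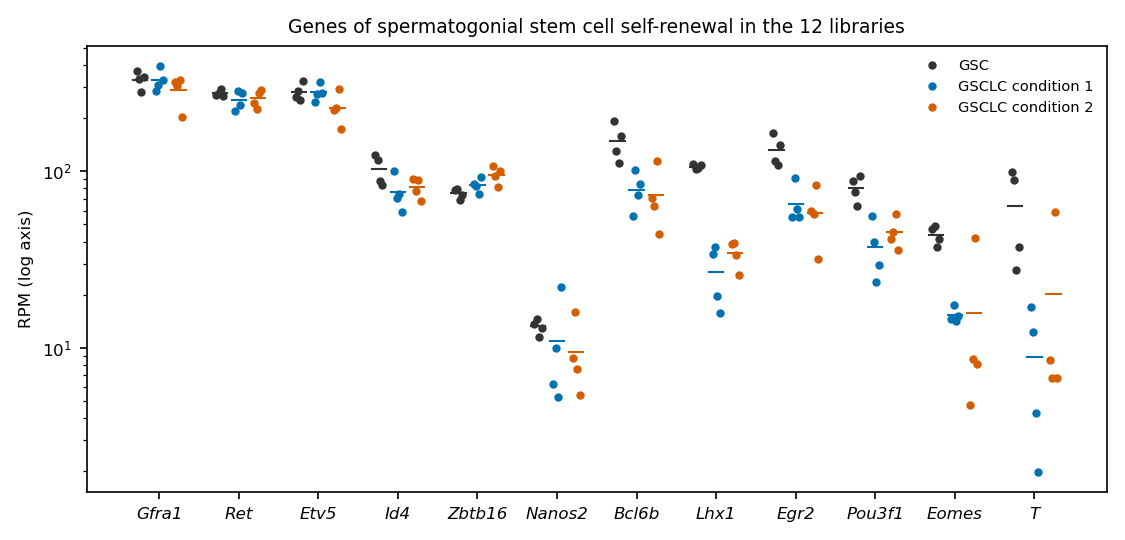
RPM on a log axis of 12 genes of spermatogonial stem cells in the 12 libraries, with 1 point per library and a bar at the mean of the 4 libraries of GSC lines, of condition 1 and of condition 2. Gfra1, Ret, Etv5, Id4, Zbtb16 and Nanos2 did not pass the test between GSCLC and GSC lines, and Bcl6b, Lhx1, Egr2, Pou3f1, Eomes and T were lower in GSCLC lines.

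The list of genes induced by FGF and GDNF signalling through ERK was lower in GSCLC lines by camera with adjusted p = 6.21e-05, and adjusted p = 0.183 with an estimated correlation. Of 19 tested members 7 fell, 1 rose and 11 did not pass, and adjusted over the list alone 8 fell and 2 rose. The immediate early gene Egr1 went from 210 ± 13.7 to 113 ± 15.3 RPM (log2 -0.93 ± 0.13, adjusted p = 0.00458). Il17rd and Spry4, which dampen FGF signalling, fell by 0.69 ± 0.13 and 1.19 ± 0.25, and the ERK phosphatase gene Dusp5 by 0.95 ± 0.22. Egr2 and Bcl6b, already given, are members too. The 2 remaining calls, chosen after their values were seen to complete the count, were Phlda1 at -0.93 ± 0.22 and Spry2, which moved against the list with a rise of 1.07 ± 0.26. Egr1 and Bcl6b lost their call without GSCLC_3 replicate 2 (adjusted p = 0.0919 and 0.0624), Spry4 without GSCLC_3 replicate 1 (adjusted p = 0.0526) and Dusp5 in 7 of the cases with 1 library left out. In replicates 1 and 2 of GSCLC_3, Egr1 stood at 183 and 89.2 RPM, Bcl6b at 115 and 44.2 RPM and Egr2 at 83.7 and 31.8 RPM. Spry2 went the other way there, at 28.8 and 36.4 RPM.

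All 9 genes from Hoxb9 to Hoxb1 fell. Hox genes encode transcription factors that pattern the body axis. The Hoxb cluster, on chromosome 11 at 96194316 to 96368254, summed to 454 ± 20.2 RPM in GSC and 112 ± 24.3 RPM in GSCLC lines. The log2 change was -2.84 ± 0.43 for Hoxb5, -2.81 ± 0.39 for Hoxb6, -2.45 ± 0.29 for Hoxb9, -2.37 ± 0.25 for Hoxb2, -2.21 ± 0.25 for Hoxb8 and -1.48 ± 0.21 for Hoxb7, with adjusted p from 0.00105 to 0.00589. Each of these calls held in 30 or 31 of 32 alternative settings, and like nearly all falls they rest on having both GSC lines. Hoxb3, Hoxb4 and Hoxb1 were chosen after their values were seen. Hoxb3 and Hoxb4 fell by 2.25 and 1.92, and Hoxb1 fell with adjusted p = 0.00632. Hoxb13, at the 5′ end of the cluster, stood at -0.71 ± 0.26 with adjusted p = 0.18. The last 300 bases of Hoxb2 are shared with the antisense transcript Hoxb3os. Of the 17 tested Hox genes of all clusters 9 fell, 0 rose and 8 did not pass, and adjusted over the list alone 10 fell and 1 rose. Camera gave adjusted p = 2.61e-07 for the list, and adjusted p = 0.183 with an estimated correlation. The Hoxa genes summed to 39.1 RPM in GSCLC_2 and 61.7 RPM in GSCLC_4, against 4.34 to 15.6 RPM in the other 4 lines, with no Hoxa gene past the threshold.

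**Figure D2:**
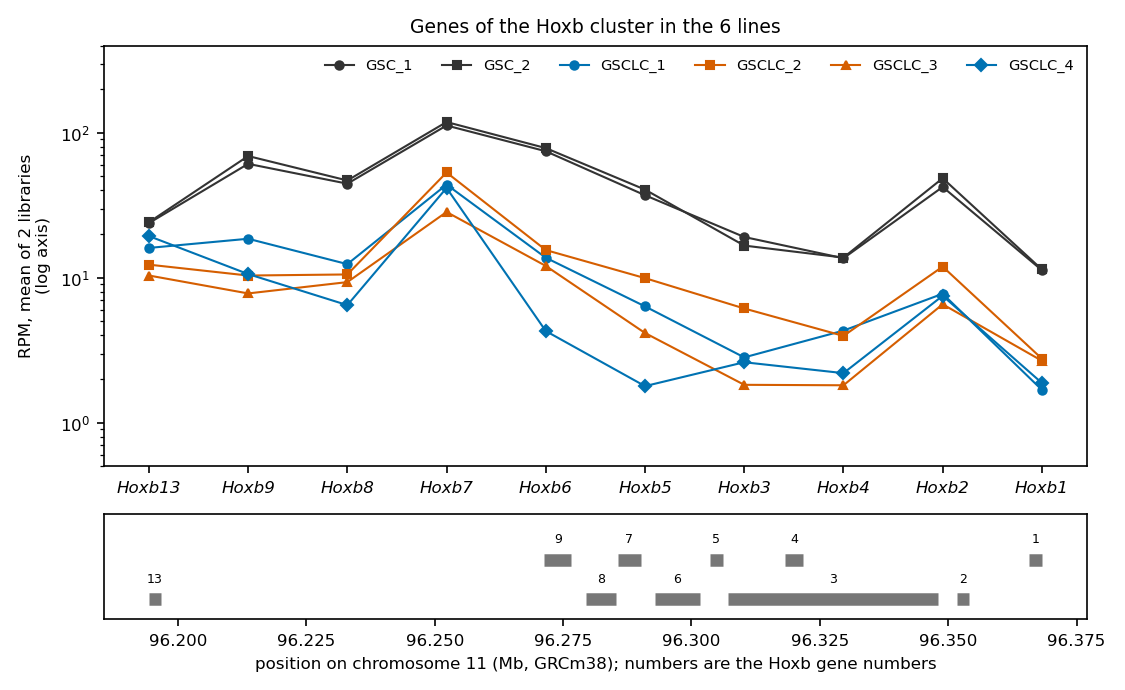
Upper panel, RPM on a log axis of the 10 Hoxb genes in the 6 lines, each point the mean of 2 libraries, in the order of the cluster. Lower panel, position of the genes on chromosome 11 in Mb; from Hoxb9 to Hoxb1 all 4 GSCLC lines lie below both GSC lines.

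The lists of germ cell identity were not called. In the germ cell core list 0 of 20 members passed under either adjustment, with adjusted p = 0.877 by camera, and the meiotic prophase list had 0 of 26 members past the threshold under either adjustment, with adjusted p = 0.148. Of 20 piRNA pathway genes Tdrd9 alone fell, and adjusted over the list alone 2 fell, with adjusted p = 0.896 for the list. The spermatogonial differentiation list had 1 of 12 members lower, the cyclin gene Ccnd1 at -1.33 ± 0.26 with adjusted p = 0.0193, also 1 when adjusted over the list alone, and adjusted p = 0.927 for the list. The end of Ccnd1 is shared with a neighbouring transcript, so its level is uncertain. Kit, the receptor of differentiating spermatogonia, was at -0.11 ± 0.22 and Stra8, induced by retinoic acid before meiosis, at -0.20 ± 0.47, neither past the threshold. Of the spermatid list 4 of 20 genes passed the filter. The DNA methylation list had 0 of 16 members past the threshold under either adjustment and adjusted p = 0.927, with the methyltransferase gene Dnmt3b at -0.05 ± 0.17, while Dnmt3l, its cofactor, reached at most 4.08 RPM and was not tested.

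Among genes of earlier stages, 2 of 16 in the pluripotency list fell. Pou5f1 fell from 26.9 ± 1.65 to 4.37 ± 2.96 RPM with adjusted p = 0.019, and Tcl1, a coactivator of Akt in early embryonic cells, fell from 195 ± 47 to 64.9 ± 17.7 RPM with adjusted p = 0.00547. The other 14 tested members did not pass, also 2 lower adjusted over the list alone, and the list had adjusted p = 0.896. Sox2, the partner of Pou5f1 in pluripotent cells, was at 33.6 ± 4.43 and 75.7 ± 45.2 RPM with adjusted p = 0.39, and Nanog reached at most 0.326 RPM in any library. Of 10 primordial germ cell genes 2 rose, Ifitm1 by 1.22 ± 0.23 and the X-linked homeobox gene Rhox9 by 1.51 ± 0.33, also 2 adjusted over the list alone, and the list stood at adjusted p = 0.0678. Of 27 imprinted genes Slc38a4 rose and H19, a non-coding RNA, fell by 1.77 ± 0.34, with 4 higher and 2 lower adjusted over the list alone and adjusted p = 0.279 for the list. H19 lost its call without GSCLC_4 replicate 1 (adjusted p = 0.0931), Ifitm1 without GSC_1 replicate 1 or GSCLC_4 replicate 2, and Rhox9 without GSCLC_2 replicate 2, GSCLC_3 replicate 1 or GSCLC_4 replicate 2. The mean, the median and the camera direction had different signs for the spermatogonial differentiation, piRNA, pluripotency, Sertoli cell and heat shock lists.

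Among markers of somatic cells, a few genes differed between the groups. Of 6 Leydig and peritubular genes 2 fell, also 2 adjusted over the list alone. These were Cyp11a1, at 25.4 ± 8.11 RPM in GSC and 0.127 ± 0.177 RPM in GSCLC lines, and Hsd3b1, a later enzyme of steroid synthesis, at 19.4 ± 1.23 RPM in GSC lines and listed at 0 in every GSCLC library. Both were high in replicate 1 of each GSC line and low in replicate 2, at 36.2, 3.23, 60.1 and 2.3 RPM for Cyp11a1 and 34.2, 2.8, 36.7 and 3.83 RPM for Hsd3b1, and neither call held on replicate 2 alone. Camera gave the list adjusted p = 0.00386, and adjusted p = 0.183 with an estimated correlation. Of 21 fibroblast markers 2 fell, the collagen gene Col5a1 by 1.13 ± 0.18 and the matrix gene Sparc by 1.09 ± 0.26, and the transcription factor Twist1 rose by 0.85 ± 0.15, with the same counts adjusted over the list alone. The list was lower with adjusted p = 0.00417, and adjusted p = 0.623 with an estimated correlation; without GSC_2 its direction turned and adjusted p was 0.936. Of 5 macrophage and endothelium markers Fcer1g, an Fc receptor chain, fell from 11.3 ± 5.76 to 0.103 ± 0.135 RPM, also 1 adjusted over the list alone, with adjusted p = 0.0813 for the list. Of 8 Sertoli cell markers Clu, a secreted chaperone, fell by 1.79 ± 0.32, at 75.3 and 130 RPM in replicate 1 of GSC_1 and GSC_2 but 19.6 and 26.0 RPM in replicate 2, and passed in 24 of 32 alternative settings but not on replicate 2 alone, while 2 rose and 2 fell adjusted over the list alone and the list had adjusted p = 0.927. With 1 library left out, Sparc lost its call in 5 cases, Clu in 3 (without replicate 1 of either GSC line or GSCLC_4 replicate 2) and Twist1 without GSCLC_4 replicate 1, with adjusted p from 0.0512 to 0.143.

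Among lists called by camera, those of growth and metabolism had smaller mean log2 changes. These were -0.25 for cholesterol synthesis and -0.26 for p53 targets. The smallest among the called lists above was -0.40, for the FGF and GDNF response. The G2/M list was higher with a mean log2 change of 0.12 and adjusted p = 0.0429, with 0 of 20 members past the threshold under either adjustment, and adjusted p = 0.247 with an estimated correlation. It was no longer past the threshold on quantile-normalised values, with adjusted p = 0.0563. Of 18 p53 targets the death effector gene Pmaip1 (-0.96 ± 0.23) and the cell cycle inhibitor gene Cdkn1a (-0.83 ± 0.20) fell, 2 as well adjusted over the list alone, with adjusted p = 0.0298 for the list and adjusted p = 0.255 with an estimated correlation. Cdkn1a passed in 9 and Pmaip1 in 12 of 32 alternative settings. The list of cholesterol synthesis, with 21 tested genes, was lower with adjusted p = 0.00386, and adjusted p = 0.436 with an estimated correlation. Of 19 glycolysis genes the aldolase gene Aldoc fell by 0.87 ± 0.16, 1 as well adjusted over the list alone, with adjusted p = 0.486 for the list. The interferon response list had 0 of 12 members past the threshold, 2 higher and 1 lower adjusted over the list alone, and adjusted p = 0.78; the heat shock list had 0 of 18 under either adjustment and adjusted p = 0.877. In all, camera called 8 of 21 lists, fry 6, and camera with an estimated correlation 0. Camera with the preset correlation also called 2 to 7 lists when another pair of lines was set apart, so its call alone is weak evidence. Fry did not call the fibroblast, cholesterol synthesis and p53 lists, with adjusted p = 0.553, 0.276 and 0.0701. It did call the macrophage and endothelium list, with adjusted p = 0.0182.

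The second question was whether the 2 ways of culturing the reconstituted testes left a mark on the GSCLC lines. Between conditions 2 and 1, limma called 0 genes, with 552 at an unadjusted p under 0.05 and 0.933 as the smallest adjusted p. Genes with low unadjusted p, all at adjusted p = 0.933 and so far from the threshold, were Cd109, a surface protein, at 34.9 RPM in condition 2 and 13.1 RPM in condition 1, the ADP/ATP carrier gene Slc25a5 (0.66 ± 0.15), Gadd45gip1 (0.64 ± 0.16, or 0.42 without GSCLC_4 replicate 1), Cnih4 (0.80 ± 0.23, or 0.28 without the same library and 1.32 without GSCLC_4 replicate 2), D14Ertd668e (0.61 ± 0.18), the RNase H2 subunit gene Rnaseh2a (0.52 ± 0.15) and Atp5g2 of ATP synthase (0.51 ± 0.15). In the other direction stood Tex18 (-0.85 ± 0.18), the homeobox gene Barhl2 (-1.15 ± 0.25), Bcar3 (-1.35 ± 0.30), the chromatin protein gene Hmgb3 (-0.61 ± 0.14), the G protein subunit gene Gng2 (-1.55 ± 0.36), Trp53inp2 (-0.75 ± 0.18), the RNA-binding protein gene Khdrbs3 (-0.94 ± 0.24) and Krr1 (-0.70 ± 0.18). Slc25a5, Gadd45gip1, D14Ertd668e and Gng2 share their ends with other transcripts. Stra8 was at 6.7 RPM in condition 2 and 17.9 RPM in condition 1, and Pou5f1 at 1.9 and 6.85 RPM, neither past the threshold.

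The change between the conditions was -0.20 ± 0.15 for Gfra1, 0.03 ± 0.14 for Ret, -0.31 ± 0.13 for Etv5, 0.18 ± 0.15 for Zbtb16, 0.11 ± 0.19 for Id4 and -0.08 ± 0.34 for Nanos2. It was -0.02 ± 0.15 for Ddx4, -0.09 ± 0.11 for Dazl, -0.56 ± 0.21 for Kit, -0.49 ± 0.58 for Sox2 and -0.11 ± 0.20 for Dnmt3b. Of the 21 lists 0 were called by camera or fry, with 2 at an unadjusted p under 0.05 and 0.385 as the smallest adjusted p, and adjusted over the list alone 2 genes passed, Stra8 and Pou5f1, both lower in condition 2. With 2 lines per condition, the 95% interval of a change reached 0.52 to either side in the median gene. For genes of at least 20 RPM it reached 0.42. These intervals may be too narrow, because their spread includes the GSC lines, which lay 39.6 apart in Euclidean distance. The lines of condition 1 lay 51.6 apart and those of condition 2 57.4 apart. Only 24% of simulated 2-fold changes were recovered, in data that also held 100 genes changed by 4-fold. Shifts of 2-fold would thus mostly be missed. The count stayed at 0 in 12 other settings of the analysis and without any single library. Without a GSCLC line, which leaves a condition with a single line, it did not always stay at 0.

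Single GSCLC lines stood apart from the GSC lines by 818 to 1891 genes, and they differed in which regions of the genome were higher. In GSCLC_2 and GSCLC_4 the genes of chromosome 6 from 80 Mb onward were higher, with a median shift against the other chromosomes of 0.50 and 0.51 on the log2 scale over 203 genes of at least 20 RPM, in which 91.6% and 86.2% of genes lay above the median of the other chromosomes. In GSCLC_3 the 414 genes of chromosome 8 were higher, with a shift of 0.50 and 91.5% of genes above. The 2 libraries of a line gave like values, 0.52 and 0.49 for GSCLC_2, 0.52 and 0.53 for GSCLC_4 and 0.50 and 0.50 for GSCLC_3. Of 100 tests of a chromosome in a line, camera called 3, chromosome 6 in GSCLC_2 (adjusted p = 5.76e-15) and GSCLC_4 (adjusted p = 8.51e-13) and chromosome 8 in GSCLC_3 (adjusted p = 6.08e-32). Chromosome 6 held 20.2% of the genes higher in GSCLC_2 and 15.2% of those in GSCLC_4, against 4.74% of the genes tested, and chromosome 8 held 31.4% of those higher in GSCLC_3, against 5.53%. The 80 Mb boundary was chosen from the profile along the chromosome.

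**Figure D3:**
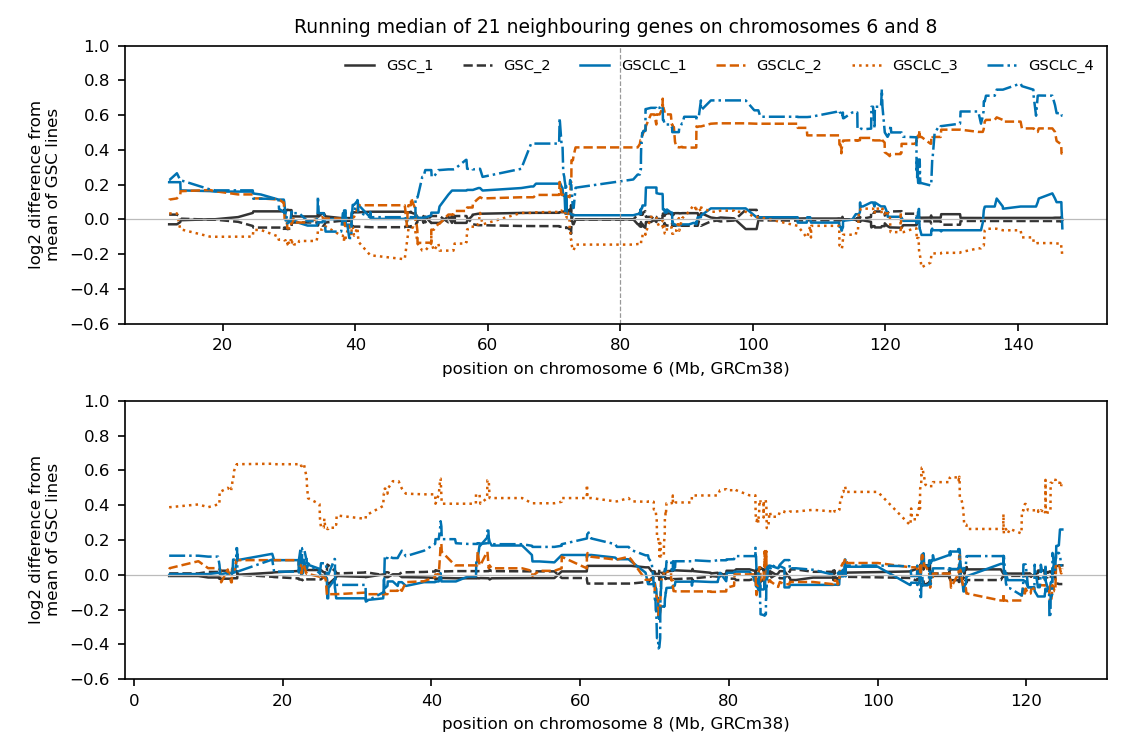
Running median over 21 neighbouring genes of the log2 difference from the mean of the GSC lines, along chromosome 6 (upper panel, dashed line at 80 Mb) and chromosome 8 (lower panel), by position in Mb, with 1 line per cell line. GSCLC_2 and GSCLC_4 rise above the other lines on the distal part of chromosome 6, and GSCLC_3 along chromosome 8.

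GSCLC_1 had 390 genes higher and 428 lower than the GSC lines. Large changes were in Sfi1 (3.12 ± 0.18) and the cartilage collagen gene Col2a1 (2.81 ± 0.36), and in Cyp11a1 (-3.74 ± 0.86, not past the threshold without GSC_1 replicate 1 or either library of GSCLC_1), Mapk10 (-2.91 ± 0.32) and Chrna4 (-2.83 ± 0.31). GSCLC_2 had 645 higher and 738 lower, with rises in Sfi1 (3.52 ± 0.18) and Crym (3.33 ± 0.30), and falls in Tdrd9 (-4.18 ± 0.39), the interferon-induced GTPase gene Gbp1 (-4.10 ± 0.36) and Sohlh1 (-3.78 ± 0.41), a transcription factor of spermatogonial differentiation. GSCLC_3 had 609 higher and 1071 lower, led by the imprinted adaptor gene Grb10 (3.52 ± 0.23), at 134 RPM against 10 to 33.7 RPM in the other lines, Crym (3.22 ± 0.30) and Slc38a4 (2.94 ± 0.19), and by Mapk10 (-4.68 ± 0.32), the inflammasome adaptor gene Pycard (-4.62 ± 0.21) and Chrna4 (-4.36 ± 0.31). GSCLC_4 had 1137 higher and 754 lower, led by the X-linked homeobox gene Rhox5 (4.54 ± 0.36), at 68.8 RPM against 1.13 to 3.27 RPM in the other lines, the homeobox gene Otx1 (3.82 ± 0.49) and Sfi1 (3.00 ± 0.18), and by Gbp1 (-4.70 ± 0.36), Hoxb6 (-3.97 ± 0.31) and Hoxb5 (-3.84 ± 0.38). The balance of directions moved with scaling: 36.3% of calls were higher in GSCLC_3 and 60.1% in GSCLC_4, against 51.3% and 50.6% after quantile normalisation and 48.8% and 47.1% after rescaling by the median ratio. Without 1 of the line's own libraries the counts fell to as few as 166 for GSCLC_1, 415 for GSCLC_2, 772 for GSCLC_3 and 744 for GSCLC_4. In this kind of test, 913 to 1006 unchanged genes were called for a GSCLC line in data simulated with a spread between lines, so these counts describe single lines and not the kind of cell.

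As a background for these comparisons, GSC_2 had 4 genes higher and 2 lower than GSC_1, while 861 unchanged genes were called for this pair in the simulated data, so the simulated spread between lines is too wide for these 2 lines. The secreted serpin gene Serpinf1 (2.11 ± 0.38), Glipr2 (1.75 ± 0.27) and the annexin gene Anxa2 (1.42 ± 0.24) were higher in GSC_2, and Utf1 (-1.74 ± 0.30), a chromatin factor of undifferentiated spermatogonia and pluripotent cells, and Aim1 (-1.42 ± 0.24) were lower, with adjusted p from 0.0186 to 0.0387. After quantile normalisation 50.0% of 6 calls were higher, against 66.7%. Without a library of either GSC line, the count was 0 or 1.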

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

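The tests of library scaling, of culture condition, of copy loss and feeder RNA at the Hoxb genes, and of Leydig cells and a batch behind the steroid genes were chosen only after the results were seen. The other tests were set down before their outcome was seen, although the regions on chromosomes 6 and 8 were already known from the profiles.

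Genes of chromosome 6 from 80 Mb onward stood higher in GSCLC_2 and GSCLC_4, and genes of chromosome 8 higher in GSCLC_3, as did no other chromosome in the GSCLC lines. Against the other line of the same condition the median differences were 0.518 in GSCLC_2, 0.438 in GSCLC_4 and 0.505 in GSCLC_3 on the log2 scale, in regions picked from the same profiles, so a test of them is no independent evidence. Extra copies may explain this, though the shifts lie under the 0.585 that 3 copies in place of 2 would give. The gene shifts spread at most 1.17 times as widely as those of other chromosomes, with a lower quartile of at least 0.203. That quartile adds no independent support, because the regions were picked for having mostly higher genes. One scaling factor per library moves all chromosomes alike and cancels in such shifts, so it cannot by itself produce them. That no other chromosome shifted by over 0.0978 adds nothing to this. GC content, transcript length or level is less likely, since the smallest difference from matched genes was 0.481, and so is culture condition, as the other line of the same condition shifted by at most 0.0344.

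On chromosome 6 the step in GSCLC_2 lay between 73.2 and 82.0 Mb and the step in GSCLC_4 at 72.6 Mb. Bootstrap limits of the start of the last gene before the step were 56.7 and 73.2 Mb in GSCLC_2 and 49.4 and 83.2 Mb in GSCLC_4. The lines are from different conditions. The group tests take every GSCLC line as independent, and whether GSCLC_2 and GSCLC_4 are independent of each other was not tested. Copy number was not measured, and DNA of these lines was not analysed here.

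The Hoxb genes, from Hoxb9 to Hoxb1, were lower in every GSCLC line. Loss of a segment that takes in most of the 2 Mb on either side is unlikely to account for this. The 67 tested genes within 2 Mb of the cluster had a median change of -0.14, with quartiles of -0.35 and 0.10. Of these genes 6 were called, all lower. A loss limited to the cluster would not move that median, so it was not tested. RNA of feeder fibroblasts in the GSC libraries could not be settled: the highest Hoxb sum of a GSC library was 1.27 times the lowest, while the sum of 7 collagen genes ran from 183 to 402 RPM. In all 8 pairs of a GSC and a GSCLC line, the Hoxb ratio exceeded the collagen ratio, with 4.47 against 0.853 for GSC_1 over GSCLC_4 and 3.43 against 3.37 for GSC_2 over GSCLC_2. Those pairs cannot decide this, because collagen RNA from another source would lower the collagen ratio but not the Hoxb ratio. They also share lines and were chosen after the values were seen. Regulation of the cluster in the cells was not tested.

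Cyp11a1 and Hsd3b1 were high in replicate 1 of both GSC lines and low in replicate 2. Contact with Leydig cells could add such transcripts. The summed RPM of the Leydig genes Star, Cyp17a1, Insl3 and Lhcgr differed between the replicates by 11.2% of the difference in Cyp11a1 in GSC_2. In GSC_1 that share was -2.47%. Cyp17a1 and Lhcgr were listed at 0 in every library, so the sum rests on Star and Insl3. Star stood at 11.3 RPM in replicate 1 and 4.08 RPM in replicate 2 of GSC_2, and at 3.91 and 4.09 RPM in GSC_1. Genes far below Cyp11a1 could not reach a large share of its difference, so the sum does not decide on Leydig cells. A batch shared by every replicate 1 library is less likely, since Cyp11a1 reached at most 0.751 RPM in replicate 1 of the GSCLC lines. A culture event in the GSC lines alone remains possible and was not tested.

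Single libraries stood apart in 14 of 255 combinations of a gene and a group of 4 libraries. They did so by a gap to the nearest other library that exceeds Dixon's 95% critical value. For independent values chance flags about 1 in 20 groups, or 12.8 here. Each group holds 2 lines with 2 replicates each, which are not independent values. That rate is therefore only a rough guide, and whether the flags exceed chance is not settled. Cyp11a1 was at 0.751 RPM in GSCLC_4 replicate 1 and 0.261 RPM in GSCLC_2 replicate 2 and at 0 in the other libraries of their conditions. Fcer1g was at 0.571 RPM in GSCLC_1 replicate 1 and 0.251 RPM in GSCLC_2 replicate 1, again against 0. These 4 values are at or under the floor of 3 reads, and with the other libraries at 0 any read stands apart, so they carry no information. T was at 58.5 RPM in GSCLC_3 replicate 1 against 6.74 to 8.52 RPM. Ccnd1 reached 132 RPM in GSC_2 replicate 2, Gng2 26.8 RPM in the same library, Il17rd 98.2 RPM in GSCLC_1 replicate 1 and Aldoc 56.1 RPM in GSCLC_3 replicate 2. Low values were those of Hoxb9 at 5.12 RPM and Gfra1 at 203 RPM in GSCLC_3 replicate 2, Cnih4 at 44.3 RPM in GSCLC_4 replicate 1 and 200.1 RPM in GSCLC_2 replicate 1, and Rnaseh2a at 66.8 RPM in GSCLC_1 replicate 1.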

How the results depend on the processing

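Most of the alternatives were fixed beforehand; those by GSC replicate, and without chromosomes 6 and 8, were added after the results were seen. edgeR and DESeq2 were not run, because whole reads could not be recovered for all genes.

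Genes called between GSCLC and GSC lines numbered 142 without a filter, 212 with at least 20 RPM, 645 on the 12 libraries with line as a random block and 1186 on libraries taken as independent. They ranged from 12 without GSC_2 to 536 without GSCLC_3, with 42 without GSC_1, 212 without GSCLC_1, 218 without GSCLC_2 and 200 without GSCLC_4 replicate 2. The filters change the set of tested genes, the 2 fits on 12 libraries take single libraries in place of line averages and another model, and the others hold fewer lines or libraries; beyond that the cause was not tested. In the fits without a GSC line, the lone one is assumed to vary like the others. Without chromosomes 6 and 8 the count was 385, with 322 shared. GSC replicate 2 alone gave 288 genes and 5 lists, replicate 1 alone 334 genes. Lists numbered 0 with an estimated correlation and 6 to 10 in the leave-outs.

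With a line or library left out, the fibroblast list ranged from adjusted p = 9.09e-10 without GSC_1 to 0.936 without GSC_2, with the direction reversed. With a line or library left out, the glycolysis list ranged from 1.07e-05 without GSC_1 to 0.917 without GSCLC_1 replicate 2, and reversed without GSC_2 at 0.00921. With 1 library left out, the difference in distance lay between 10.6 and 15.1, always with p = 0.0667 by the exact permutation test.

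Between conditions, gene counts ran from 0 without GSC_1 replicate 1 to 11 without GSCLC_2. Called lists were 2 without a filter and 0 to 4 in the leave-outs, with 4 without GSCLC_3.

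Without a filter GSCLC_1, GSCLC_2 and GSCLC_3 had 349, 811 and 1095 genes against the GSC lines, and GSC_2 had 0 against GSC_1. Those fits correct for more genes. Without a trend GSCLC_1 had 531 and GSC_2 against GSC_1 had 1. Leave-outs gave 166 to 911 for GSCLC_1, 415 to 1480 for GSCLC_2, 772 to 1845 for GSCLC_3, 744 to 1955 for GSCLC_4 and 0 to 9 for GSC_2 against GSC_1.

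With the replicate number as a block beside line, the calls were 592 between GSCLC and GSC. Replicates of different lines were not paired in the values, with correlations of -0.22 to 0.20 over 15 pairs of lines.

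Of 3290 recomputed values of named genes 3023 kept their side of the threshold, called or not, 266 lost a call, 1 gained one and 0 calls reversed, while 34 uncalled values changed sign. Of 1214 for lists 1152 kept their side, 36 lost a call, 24 gained one and 2 reversed, while 108 uncalled ones changed direction. At these depths genes under 5 RPM in 11 or 12 libraries were not tested except without a filter.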

Other observations

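The genes in this part were chosen only after the results were seen; the count of neighbours and the regrouping of lines were set down before their outcome was seen, although side-by-side calls had been noticed.

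Called genes often followed one another in the order of tested genes along a chromosome, counted without a limit on their distance. Dlx3 and Dlx4, homeobox genes on chromosome 11, fell by 1.97 and 1.36. Dmrt2, a transcription factor gene of chromosome 19, fell by 2.39 beside the non-coding gene 2610016A17Rik, and Col2a1 rose by 1.85 beside Tmem106c. Without the Hoxb genes, 35 of 338 called genes lay next to a gene called in the same direction, where shuffled calls gave 10.2 on average, with p = 0.0001 by permutation, the smallest that 10000 shuffles allow. Shared regulation may contribute where such genes lie close together, but the count takes in distant genes and does not show it. Overlapping or shared transcript ends, which were not tested here over all pairs, may be another cause.

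Prrx2, a homeobox gene of mesenchyme, stood at 63.0 to 77.5 RPM in the GSC libraries and 8.25 to 20.4 RPM in the GSCLC libraries, and Sall2, a zinc finger gene, at 5.66 to 15.7 RPM and 26.7 to 52.2 RPM. Cdk6, a cyclin-dependent kinase gene, went from 1.48 to 3.59 RPM in GSC libraries to 10.5 to 27.5 RPM in GSCLC libraries.

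Aldh1a1, a retinaldehyde dehydrogenase gene, followed Cyp11a1 between the replicates, with 16.9 and 1.94 RPM in GSC_1 and 44.3 and 2.30 RPM in GSC_2, as did Sfrp4, a secreted Wnt antagonist gene, with 9.45 and 0.431 RPM and 29.0 and 3.32 RPM. Exchanged roles of the lines were tried for the 2 group comparisons. Among the 15 ways to set 2 of the 6 lines apart, the real one alone gave as many as 356 genes, and the next gave 48, that of GSCLC_2 with GSCLC_4, of which 15 lie on chromosome 6. For lists it was 1 of 15 as well, but with 8 against 2 to 7 in the other ways. GSC_1 with GSCLC_2 gave 7 lists and 0 genes. List calls by camera thus also arose under arbitrary groupings, and their number barely sets the real way apart. Between conditions the real way gave 0 genes and 0 lists, a result that 3 of 3 ways reach for genes and 3 of 3 for lists by construction, so that count tells nothing. Setting GSCLC_1 and GSCLC_3 against GSCLC_2 and GSCLC_4 gave 84 genes, 27 of them on chromosome 6, and 0 lists, which points to a structure of the samples. Setting GSCLC_1 and GSCLC_2 against the others gave 1 gene and 5 lists. In each case the ways are too few for a share under 0.05.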
